A study of Oryza sativa with 8 samples.

How the data were processed

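Gene expression in rice (Oryza sativa, cultivar I Kong Pao) was measured on 8 arrays with 2 channels each. Per the labels, seedlings 25 days old were kept in hydroponic solution with 0 or 125 mg/L ferrous iron for 3 days or for 3 weeks, and total RNA was taken from the roots or the shoots of pooled plants. Every array carried control RNA in the green channel and RNA of iron-exposed plants in the red channel, both from the same tissue and time. The arrays fell into 4 groups of 2 (shoots at 3 days, shoots at 3 weeks, roots at 3 days, roots at 3 weeks), with 1 array for each biological replicate. The dyes were never exchanged, so a dye bias of a probe stays in the response of a group and, if constant, cancels in a difference between groups. Per the file headers, replicate 1 of every group was on slide 1 and replicate 2 on slide 2, so that the slide and the replicate plants cannot be told apart.

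Per the file headers and the submitters' processing notes, the arrays were read with Agilent Feature Extraction 9.1, and each file gives the mean intensity of every spot and the median intensity of its local background in both channels, as scanned. The authors' processed value in the same files is a log10 ratio of red over green, made after background subtraction with spatial and multiplicative detrending and after linear and lowess dye normalization, with substitute values for dim signals. The deposited table of the whole series holds these log10 ratios, with a largest difference of 0 from the values in the scanner files. The arrays held 44407 spots, of which 42990 were not controls: 21495 probes, each printed on 2 spots. Each probe carried its own full-length cDNA identifier and the description of its closest database entry, which often belongs to another species, and for 5565 probes the description was only that of an unknown expressed protein. Of the identifiers, 0 matched an entry of the reference annotation of the assembly ASM3414082v1, so genes are named by identifier and by that description.

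Spot and background intensities were corrected with the normexp method (offset 50) and normalised within each array by loess in limma 3.58.1 under R 4.3.3, with the package data.table (version 1.17.8). Spots that the scanner software had marked as outliers were left out, and both spots of a probe were averaged. Control and iron levels in the text are log2 channel levels after loess and after quantile normalization of the average intensities between arrays. The log2 ratios were not normalized between arrays. Probes well above background in 1 channel on both arrays of at least 1 group were kept, which left 18737 probes, 18694 of them with a ratio on all 8 arrays. A single limma model with 4 group means and 4 residual degrees of freedom (2.68 prior degrees of freedom) gave each group's mean log2 ratio of iron over control against 0 and the 4 differences between groups, with two-sided moderated tests and Benjamini-Hochberg adjustment over all probes at a threshold of 0.05. Standard deviations in the text are over the 2 arrays of a group, and the small number of arrays limits their precision. Where the iron channel of an iron uptake gene was not well above background, the fitted fold is not a bound. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.

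Before the data were examined, 30 gene lists were written as words to be found in the descriptions, and the rule for named genes was fixed: the probes with the largest rise and fall among those past the threshold, plus OsFER1, OsFER2, OsIRO2, OsIRT1, OsNAS1 and OsNAS2 whether called or not. As the iron lists and the lists of root transporters and leaf senescence had been written by locus, they could not be matched. The lists of iron uptake, iron storage and root nitrate transporters were then rebuilt from the descriptions, and leaf senescence and OsIRO2 were not analysed here; no probe was described as OsFER1. The 1 probe of the uptake words that was described as an isopentenyl enzyme was taken out of the uptake list after the list's first result had been seen. With it the list had 20 members and a median of -0.20 in roots at 3 days (adjusted p = 0.00028), against 19 members and -0.24 (adjusted p = 7.6e-05) as reported. Because no probe passed the threshold, named genes other than the 6 in the rule were chosen after their values had been seen, from probes with an unadjusted p up to 0.01 in a group or a difference, from probes over 2-fold on both arrays with the same sign, and from the members of a called list or of the iron lists.

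Gene lists with at least 5 measured members (29 in all) were tested with camera at its preset correlation of 0.01 on all their probes with a ratio on all 8 arrays, adjusted over the lists within each comparison. Each list was tested again with a correlation estimated from the data, with fry and with the slide as a block. The values of fry are those for a shared direction unless its mixed test, which ignores direction, is named. The list of iron storage (3 members) and others with fewer than 5 members were too small for the test. Every probe had its own cDNA identifier, so that taking 1 probe per gene by identifier left nothing out. Probes of a list can share a description and can stand for the same gene, as in the uptake list with 19 probes of 9 descriptions.

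The steps were tested on simulated data, whose spread came from the joint fit of all 8 arrays (20 simulations, 18694 probes). Changes were put into roots at 3 days. Genes and arrays were drawn independently, so that what the arrays of a slide share was left out. Of probes changed 1.5-fold, 2-fold, 4-fold and 8-fold, limma called 1.7%, 35.7%, 86.6% and 95.1%, with 5.45 false calls on average. Lists of 40 genes shifted by 0.3 on the log2 scale were called in 100% of cases by camera with the preset correlation, in 98.8% with an estimated correlation and in 98.8% by fry, and lists with no shift in 0.62%, 0% and 1.88%. Whether the replicate numbers paired the groups was checked from the deviations of the arrays from their group means, whose correlation across probes between groups ran from 0.04 for shoots at 3 days and 3 weeks to 0.37 for roots at 3 days and 3 weeks. As this shared part varied, the slide entered as a block only among the alternatives, and the main tests leave that part in the residual spread. With the block, 1569, 1712, 816 and 958 probes had an unadjusted limma p under 0.05 in the 4 groups (in the order given above), more than without it in each.

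The alternatives were: no background correction, the scanner software's own log ratio, the authors' deposited log ratios of the whole series, median centring in place of loess, quantile normalization of the average intensities between arrays, no filter and a strict filter on dim probes (6664 probes), 1 probe per gene, a minimum change of 2-fold, the slide as a block, the arrays of a comparison alone, and leaving out each array in turn. Scaling between arrays, array weights, 1 probe per description in a list (the brightest), a trended and robust spread, slide 2 alone as values with no test, and the list test on the differences between groups were added after the data were examined.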

Results

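The series compared the transcripts of iron-exposed and control rice seedlings on 8 arrays: 2 of shoots after 3 days, 2 of shoots after 3 weeks, 2 of roots after 3 days and 2 of roots after 3 weeks of 125 mg/L ferrous iron. The series title names its question as the impact of iron toxicity on the rice plant. Signal differed between the slides. On slide 1, which held replicate 1 of every group, the median brightness above background of the iron channel was 16.05, 33.57, 43.29 and 14.48 units in the order of groups just given, against 233.1, 167.3, 177.3 and 195.5 on slide 2, which held replicate 2. The share of iron-channel spots well above background ranged from 36.1% to 56.7% on slide 1 and from 68.9% to 90.6% on slide 2, and that of the control channel from 65.7% to 88.9% over all arrays.

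Genes of the photosystems and the light-harvesting complexes separated the tissues. The median control level of the 37 probes was 13.92, 12.86, 13.40 and 11.98 on the log2 scale on the 4 shoot arrays and 6.81, 7.62, 7.91 and 7.78 on the 4 root arrays. The median of the 3 probes of nitrate transporters, listed as root markers, did not separate them, with median control levels from 6.51 to 7.26 over all arrays. Singly, the Nrt2 probes had higher mean control levels in roots at 3 days and 3 weeks than in shoots. These were 7.06 and 6.94 against 6.35 and 6.42 for AK072215, and 7.52 and 7.66 against 6.75 and 6.93 for AK109733. The nar2.1-like AK109571 did not, at 6.82 and 6.61 against 6.96 and 6.84.

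Log2 ratios of iron over control shared more between arrays of a slide than between the replicates of a group. Across probes, which are not independent replicates, Pearson's r between the 2 arrays of a group had a mean of 0.03 over the 4 groups (range -0.13 to 0.16). Between different groups it had a mean of 0.40 on slide 2 (range 0.23 to 0.52), 0.08 on slide 1 (range -0.12 to 0.40) and 0.00 across slides (range -0.19 to 0.07). The values of both replicates are therefore given below for each gene list that passed by camera in a group, and each is also the value within a slide.

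**Figure D1:**
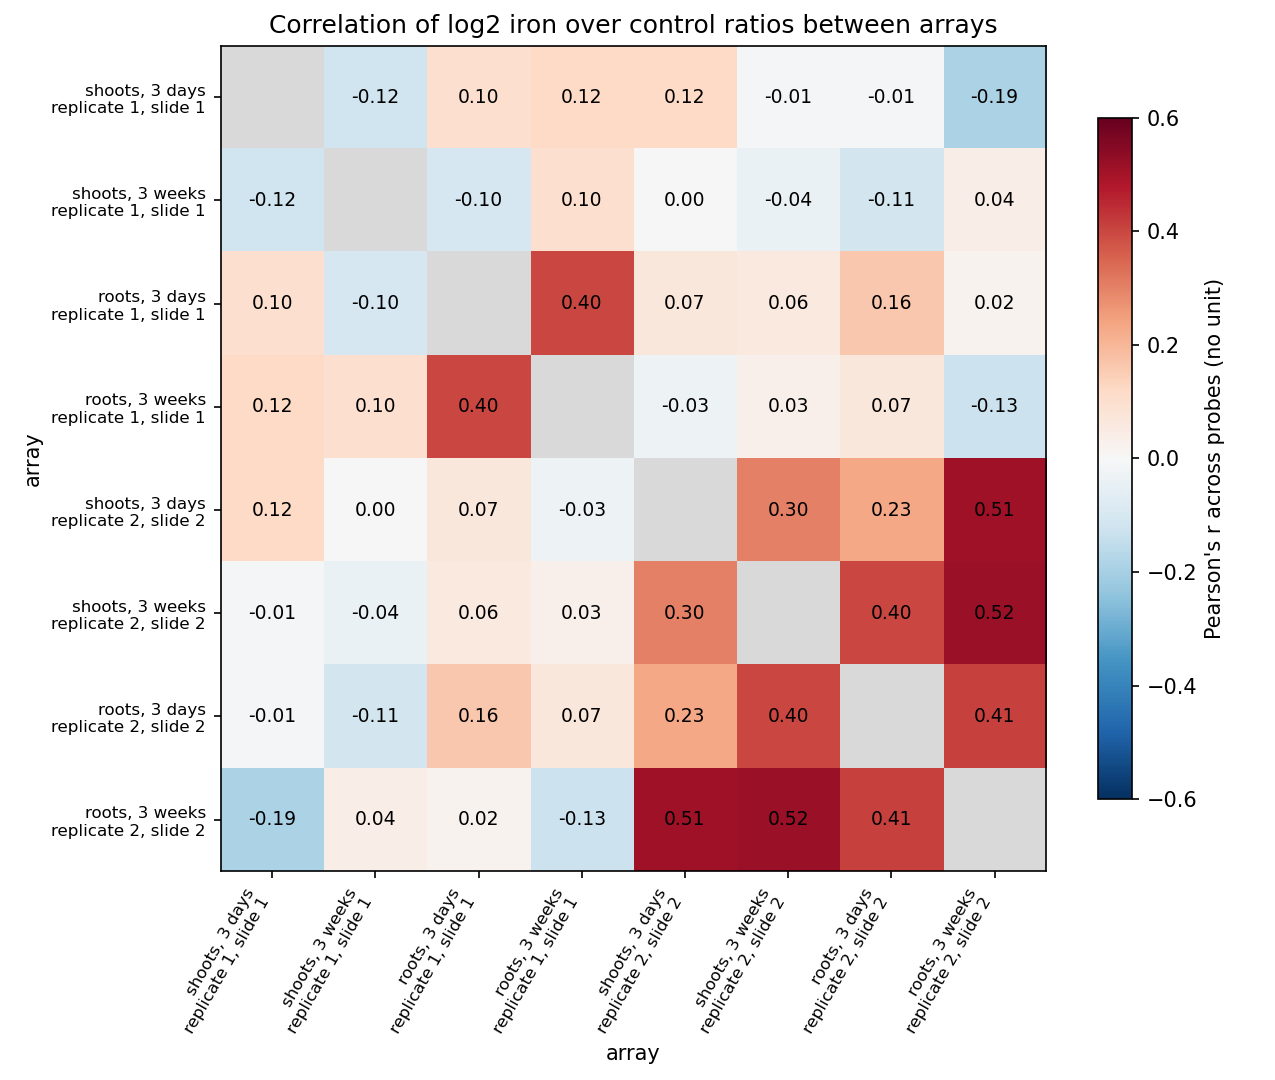
Pearson's r across probes (colour, no unit) between the log2 iron over control ratios of every pair of the 8 arrays, ordered by slide; grey cells are an array with itself. Pairs on slide 2 range from 0.23 to 0.52, while the replicates of a group range from -0.13 to 0.16.

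In shoots after 3 days of iron, genes of photosynthesis fell and the ferritin transcript Fer2 was higher on both arrays. Of the 37 probes of photosystem and light-harvesting genes, 32 were lower and 5 higher, with a median log2 ratio of -0.55 (-0.40 on replicate 1, -0.64 on replicate 2; camera adjusted p = 1.6e-09, adjusted p = 0.56 with an estimated correlation). Examples were the photoprotective 22 kDa protein of photosystem II (AK058284), 2.18-fold lower (log2 -1.12 ± 0.27, SD, n = 2), and a chlorophyll a/b-binding protein (AK058293), 1.95-fold lower (-0.96 ± 0.10). Outside the list, the gamma subunit of the chloroplast ATP synthase (atpC, AK064835) was 2.22-fold lower (-1.15 ± 0.08). Fer2 (AK102242), an iron storage protein, was 3.08-fold higher (log2 1.62 ± 0.37, SD, n = 2, limma adjusted p = 0.13). Its log2 ratio depended on the processing and ran from 0.56 to 1.88 over all settings.

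The genes of chlorophyll and heme synthesis fell as a list in these shoots, with a median of -0.47 over 12 probes (-0.19 and -0.38 on the replicates; 7 lower, 5 higher; camera adjusted p = 0.0057, adjusted p = 0.56 with an estimated correlation). Among them were a magnesium chelatase subunit (AK067323, log2 -0.99 ± 0.04) and glutamyl-tRNA reductase (AK099393, -0.96 ± 0.02), which act at the branch towards chlorophyll and at the start of the pathway. The Calvin cycle and photorespiration list fell as well, with a median of -0.29 over 27 probes (17 lower, 10 higher; camera adjusted p = 0.0063, adjusted p = 0.58 with an estimated correlation). Phosphoribulokinase (AK099461, -1.17 ± 0.24), glycolate oxidase (AK062189, -1.28 ± 0.52) and a small subunit of Rubisco (AK068266, 2-fold lower, SD 0.53) were examples, but the list median was 0.08 on replicate 1 and -0.55 on replicate 2, and 0.15 under the strict filter on dim probes. ABC transporters fell by a small amount (median -0.06 over 37 probes; -0.07 and -0.19 on the replicates; camera adjusted p = 0.025, adjusted p = 0.65 with an estimated correlation), with AK099974 at -1.06 ± 0.23. Their median was -0.43 under the strict filter, and the list did not pass with the scanner's ratio (-0.21) or under median centring (-0.11).

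Cytosolic ribosomal proteins rose in the same shoots, with a median of 0.22 over 27 probes (0.18 and 0.24 on the replicates, 0.05 and not past the threshold under median centring; 23 higher, 4 lower; camera adjusted p = 0.0011, adjusted p = 0.66 with an estimated correlation); the ribosomal protein S17 (AK070753) stood at 0.87 ± 0.24. Metallothioneins, small cysteine-rich proteins that bind metals, rose on the mean of the arrays, with a median of 1.08 over 7 probes (camera adjusted p = 0.0057, adjusted p = 0.56 with an estimated correlation). This rested on replicate 1, where the median was 2.35 against -0.18 on replicate 2, and the type 1 metallothionein AK103445 had ratios of 4.69 and -0.12.

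Single probes with an unadjusted limma p under 0.05 in these shoots were mostly lower. The probes named here were not ranked by p. The plastid omega-3 fatty acid desaturase FAD7 (AK061531), which makes trienoic lipids, was 2.79-fold lower (log2 -1.48 ± 0.12, SD, n = 2; limma adjusted p = 0.13), and a FAD8-like desaturase (AK058242) stood at -1.99 ± 1.59. CLA1 (AK064944, the transketolase-like enzyme of plastid isoprenoid synthesis) stood at -1.49 ± 0.34, the chloroplast RelA homologue Os-RelA2 (AK058438) at -1.56 ± 0.73, germin-like protein 5 (AK065284) at -1.45 ± 0.25 and a high light-induced lectin-like protein (AK099576) at -1.35 ± 0.04. Higher were a transcript similar to barley Ids3 (AK060318, 1.01 ± 0.02), a beta-glucanase (AK070056, 1.19 ± 0.59) and a Bowman-Birk proteinase inhibitor (AK067257, 1.06 ± 0.49). A transcript similar to the yeast vacuolar iron transporter CCC1 (AK071589, 1.41 ± 0.53, limma unadjusted p = 0.02) was over 2-fold higher on both arrays. The second ferritin probe (AK106026) had ratios of -0.35 and 1.24, and OsNAS3 (AK070656) of 1.03 and -0.45. No probe passed the threshold in limma (0 of 18737, smallest adjusted p = 0.126), while 1264 had an unadjusted p under 0.05 (361 higher, 903 lower) against 937 expected by chance (753 under median centring). Over 2-fold on both arrays were 50 probes, of which 41 (82%) moved the same way, 35 of them lower.

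Adjusted over the list alone, 5 of the photosystem genes, 10 of the Calvin cycle genes, 3 of the chlorophyll and heme genes and 2 of the ABC transporters passed, against 0 in each adjusted over all probes. None of the 6 lists passed by fry for a shared direction (smallest adjusted p = 0.27). By its mixed test, which ignores direction, 4 passed: the photosystem, Calvin cycle and ABC transporter lists (adjusted p = 0.0031 each) and chlorophyll and heme synthesis (0.012). The photosystem median ran to -1.45 under median centring (-0.40 under the strict filter on dim probes). Under that filter the photosystem, Calvin cycle and chlorophyll lists no longer passed. Without replicate 2 of this group 2 lists passed. With 1 probe per description the Calvin cycle list no longer passed (-0.26), and the metallothioneins, 7 probes of 3 descriptions, were too few.

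**Figure D2:**
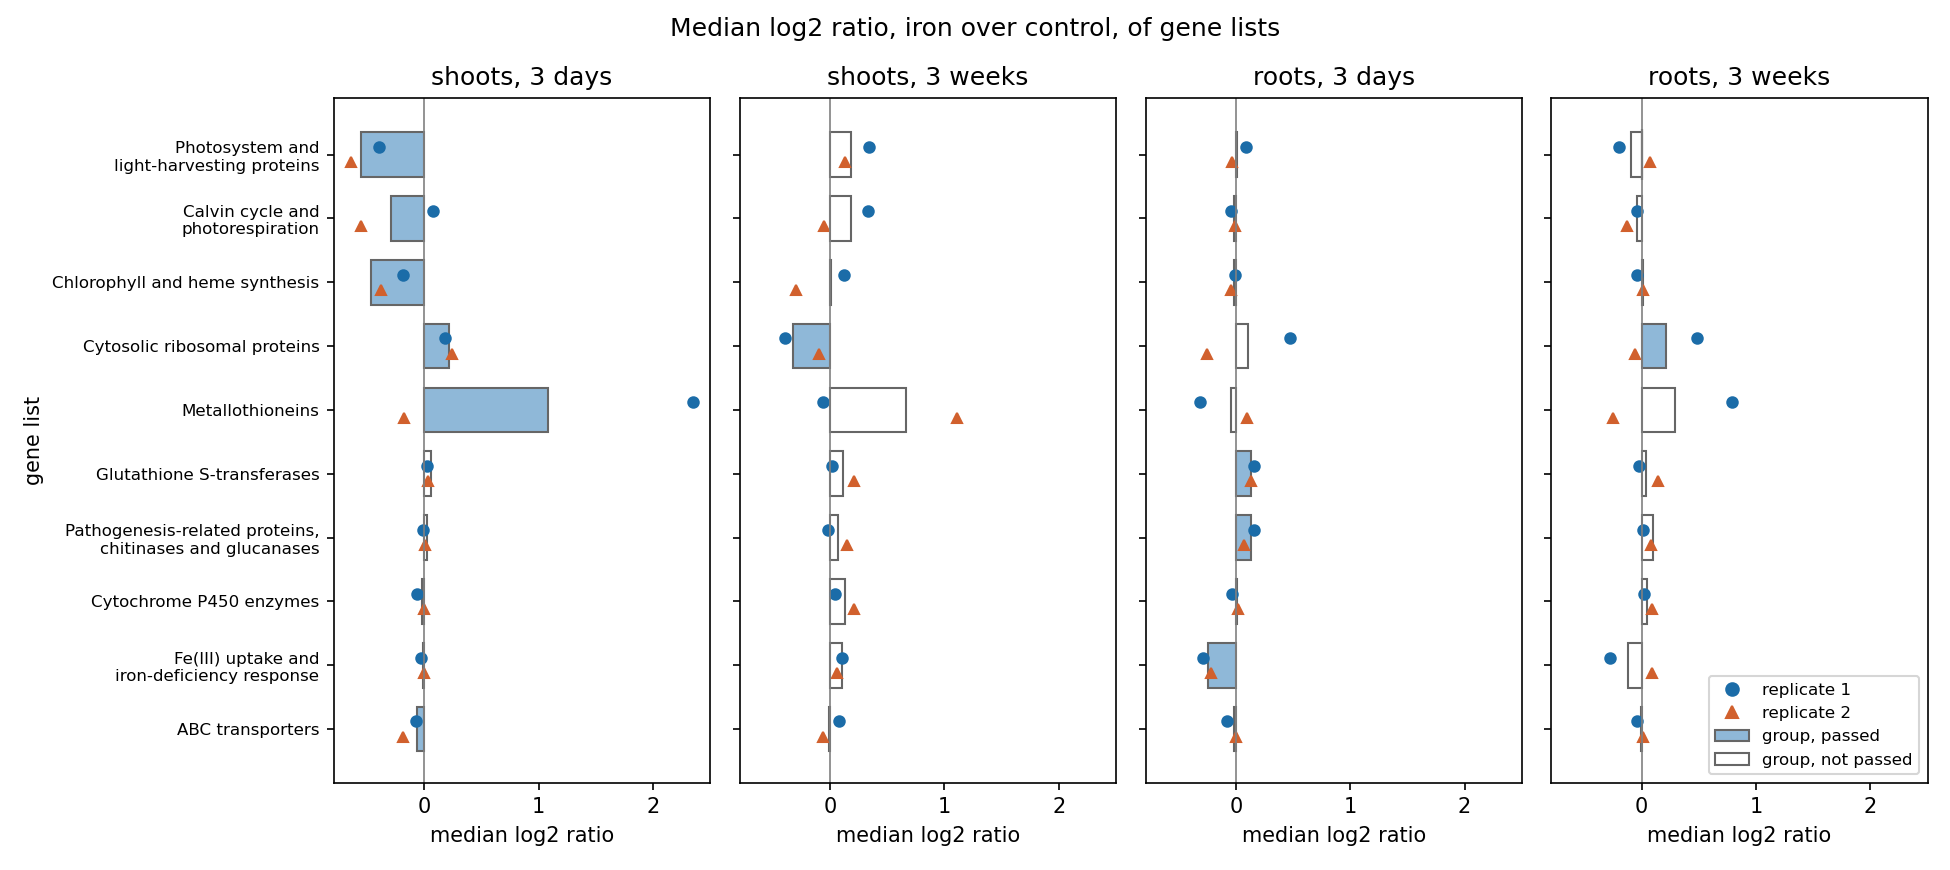
Median log2 ratio of iron over control for 10 gene lists in each group (bars; filled where camera with the preset correlation passed), with the median on replicate 1 (circles) and replicate 2 (triangles). Photosystem genes lie at -0.55 in shoots at 3 days and 0.18 in shoots at 3 weeks, and the metallothionein bar of shoots at 3 days averages 2.35 and -0.18.

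In shoots after 3 weeks, ribosomal protein genes fell and the phosphate transporter OsPT1 was higher on both arrays. OsPT1 (AK063990) was 2.52-fold higher (log2 1.33 ± 0.09, SD, n = 2; limma adjusted p = 0.28). A purple acid phosphatase (AK071643) stood at 1.13 ± 0.11, a transcript similar to ids4 (AK107245) at 2.23 ± 1.40 and a ribonuclease (AK058502) at 1.71 ± 0.83. The list of nitrate, ammonium and phosphate transporters, to which OsPT1 belongs, did not pass by camera (median 0.09, adjusted p = 0.50) and passed by the mixed test of fry, which ignores direction (2.3e-05). Adjusted over that list alone 2 members passed. Of 27 probes of cytosolic ribosomal proteins, 22 were lower and 5 higher, with a median of -0.32 (-0.39 on replicate 1, -0.10 on replicate 2; camera adjusted p = 0.0015, adjusted p = 0.80 with an estimated correlation), and the large-subunit protein L6 (AK067896) stood at -0.65 ± 0.43. The acidic ribosomal protein P0 (AK064857), outside the list, stood at -0.61 ± 0.33.

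Fer2 stood at 0.43 ± 0.44 in these shoots and the second ferritin probe (AK106026) at 0.42 ± 0.52 (-0.11 under median centring), while the Ids3-like transcript (AK060318) stood at 0.94 ± 0.41 and OsNAS3 (AK070656) at 0.74 ± 0.45. Other transcripts over 2-fold higher on both arrays were a germin (AK059872, 1.53 ± 0.35), the sugar transporter homologue MtN3 (AK103266, 1.32 ± 0.07), a lipid transfer protein (AK063196, 1.25 ± 0.10), a putative protein kinase (AK059727, 1.43 ± 0.26) and a putative prolyl endopeptidase (AK065953, 2.55 ± 0.89). The chloride channel homologue CLC-Nt2 (AK101523) was 2.17-fold lower (-1.12 ± 0.14). Photosystem genes had a median of 0.18 (camera adjusted p = 0.063), Calvin cycle genes 0.18 (0.47), metallothioneins 0.66 (0.27; -0.06 and 1.11 on the replicates), amino acid synthesis genes -0.16 (0.063) and the iron uptake list 0.10 (0.71), none past the threshold.

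In limma 0 of 18737 probes passed in shoots at 3 weeks (smallest adjusted p = 0.281), with 1337 at an unadjusted p under 0.05 (1065 higher, 272 lower; 79.7% higher under loess and 17.5% under median centring), and 1 passed with the slide as a block, the prolyl endopeptidase (adjusted p = 0.04). The 1337 lay above the 937 expected by chance, while 269 under median centring, 525 with the scanner's ratio and 577 with scaling between arrays lay below. Over 2-fold on both arrays were 64 probes, of which 25 (39.1%) moved the same way, 24 of them higher. The ribosomal list was the 1 list called, by camera only (fry smallest adjusted p = 0.20), and without replicate 1 of this group its median was -0.10 and it no longer passed.

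In roots after 3 days, the list of iron uptake genes fell, while glutathione S-transferases and pathogenesis-related proteins rose. OsNAS2 (AK112011) and OsNAS1 (AK112069), which make the phytosiderophore precursor nicotianamine, were 9.53-fold and 7.41-fold lower (log2 -3.25 ± 3.00 and -2.89 ± 2.37, SD, n = 2; limma adjusted p = 1 for both). The drop was seen on both arrays, at -1.13 and -5.37 for OsNAS2 and at -1.22 and -4.56 for OsNAS1, whose iron channel was well above background on 1 of the 2. Of 2 transcripts similar to maize yellow stripe 1, the transporter of iron-phytosiderophore complexes, AK063464 was 6.07-fold lower (-2.60 ± 0.89, with an iron channel not well above background on either array) and AK070304 2.78-fold lower (-1.48 ± 0.09). The list of iron uptake and deficiency genes had a median of -0.24 and a mean of -0.66 over 19 probes (-0.29 on replicate 1, -0.22 on replicate 2; 14 lower, 5 higher; camera adjusted p = 7.6e-05, adjusted p = 0.48 with an estimated correlation). In the same list OsIRT1 (AK103730) had ratios of -0.74 and 0.16. The Ids3-like AK060318, the highest member of the list here, had ratios of 0.26 and 0.77. It was above 0 on all 8 arrays, and a dye bias of this probe was not tested. The 6 probes described as OsNramp1 ran from -0.82 ± 0.31 (AK103557, iron channel not well above background) to 0.17 ± 0.20 (AK102180, the brightest). The ratio of AK103557 depended on the processing, from -4.31 to -0.60 over all settings.

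Of the iron storage transcripts, Fer2 was 2.65-fold higher in these roots (log2 1.41 ± 0.06, SD, n = 2, limma adjusted p = 0.30). Over all settings its log2 ratio ran from 0.63 to 2.27, a wider range than that of the replicates. The CCC1-like transcript (AK071589) stood at 1.77 ± 1.43. The second ferritin probe (AK106026) stood at 0.30 ± 0.33 and OsNAS3 (AK070656) at 0.23 ± 0.24.

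**Figure D3:**
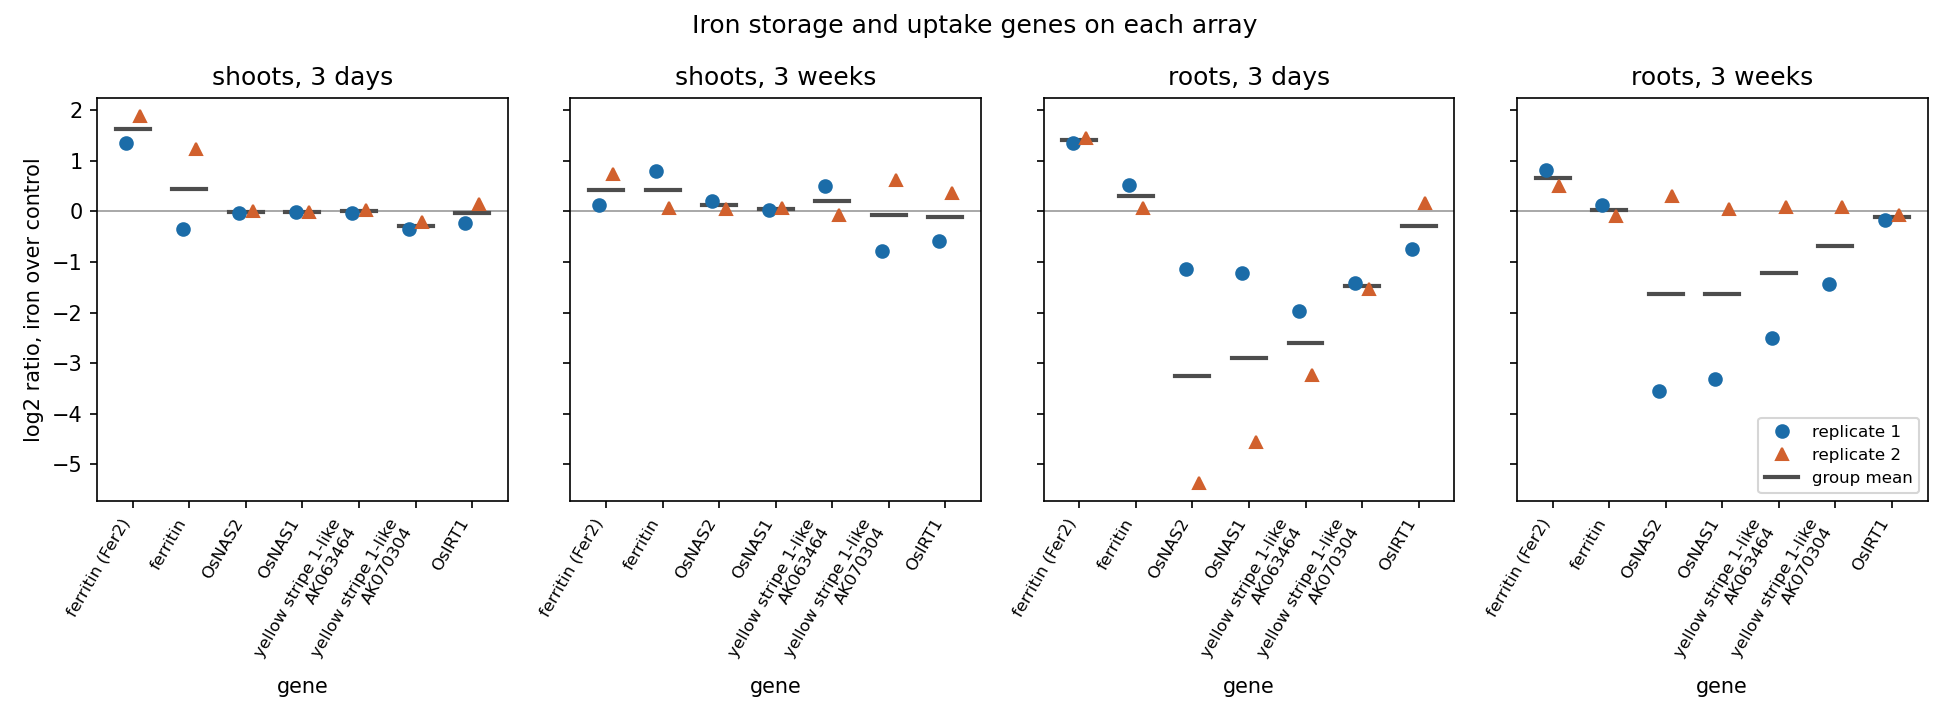
Log2 ratio of iron over control for 7 iron storage and uptake genes on each array (circles, replicate 1; triangles, replicate 2; lines, group means). OsNAS2 lies at -1.13 and -5.37 in roots at 3 days and at -3.56 and 0.30 in roots at 3 weeks, while Fer2 lies above 0 on all 8 arrays. A dye bias of the Fer2 probe was not tested.

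Glutathione S-transferases, which conjugate reactive compounds, rose in these roots: 36 of 45 probes were higher, with a median of 0.13 (0.16 and 0.13 on the replicates; camera adjusted p = 3.3e-08, adjusted p = 0.47 with an estimated correlation). OsGSTU5 (AK103316, 1.44 ± 0.81) and OsGSTU3 (AK107435, 1.32 ± 0.55) were examples. Pathogenesis-related proteins, chitinases and glucanases rose as well, with 42 of 55 probes higher and a median of 0.13 (0.16 and 0.07; camera adjusted p = 1.4e-05, adjusted p = 0.48 with an estimated correlation). Members with large ratios were Bowman-Birk proteinase inhibitors, which the list also held (AK064050, 2.75 ± 0.84, and AK067257, 1.41 ± 0.56), and a chitinase (AK102505, 0.90 ± 0.16). Outside the list, 3 probes of the probenazole-inducible protein PBZ1 (AK071613, 3.30 ± 2.28, AK061606, 2.64 ± 1.63, and AK099157, 2.57 ± 1.42) and a beta-1,3-glucanase (AK104472, 2.02 ± 1.25) were higher on both arrays. Cytochrome P450 enzymes passed on their mean of 0.18, while their median was 0.01 over 89 probes (-0.03 and 0.02 on the replicates), 48 higher and 41 lower (camera adjusted p = 0.025, adjusted p = 0.65 with an estimated correlation). The P450 with the largest ratio, AK106424, was 9.01-fold higher (log2 3.17 ± 0.55, SD, n = 2; limma adjusted p = 0.16).

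Other transcripts higher on both root arrays at 3 days were RAB24 (AK073273, 3.04 ± 0.25), 3 peroxidases (AK069456 at 2.33 ± 1.27, AK103641 at 1.58 ± 0.23 and AK064619 at 1.56 ± 0.41), a laccase (AK103094, 1.46 ± 0.21), a flavanone 3-hydroxylase-like protein (AK068438, 1.72 ± 0.16) and an auxin-induced protein (AK103553, 1.90 ± 0.64). The class III peroxidase list did not pass by camera (median 0.04, adjusted p = 0.19). Lower were the ethylene-forming enzyme ACO1 (AK105491, -1.86 ± 0.35), the peroxidase WSP1 (AK109340, -1.35 ± 0.55) and the transcription factor MYB59 (AK111626, -1.24 ± 0.24).

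No single probe passed in roots at 3 days (0 of 18737 in limma, smallest adjusted p = 0.164), and 579 had an unadjusted p under 0.05 (357 higher, 222 lower; 61.7% higher under loess and 9.6% under median centring), fewer than the 937 expected by chance. The count was 993 under median centring, 1163 with the scanner's ratio and 1249 with scaling between arrays, each above 937. The replicates still moved together for large ratios, since 60 of the 64 probes over 2-fold on both arrays (93.8%) had the same sign, 52 higher and 8 lower. Adjusted over the list alone, 7 glutathione S-transferases, 3 pathogenesis-related genes and 3 P450 genes passed and 0 iron uptake genes. The 4 lists did not pass by fry for a shared direction (smallest adjusted p = 0.66). By its mixed test the glutathione S-transferases (adjusted p = 0.0065), the P450 enzymes (0.002) and the class III peroxidases (5.6e-05) passed, and the other 2 of the 4 did not. The P450 list was lost with the slide as a block (adjusted p = 0.05), and the uptake list was lost under the strict filter, under median centring and without replicate 2 of this group (medians -0.19, -0.72 and -0.29). With 1 probe per description the P450 list was lost (0.04) and the uptake list, 9 descriptions, passed (-0.31). Without replicate 2 of this group 14 single probes passed.

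In roots after 3 weeks, the iron uptake genes were lower on 1 of the 2 arrays. OsNAS2 had log2 ratios of -3.56 on replicate 1 and 0.30 on replicate 2, OsNAS1 of -3.31 and 0.04, and the yellow stripe 1-like AK063464 and AK070304 of -2.51 and 0.09 and of -1.44 and 0.08. The iron channel of OsNAS1, AK063464 and AK070304 was well above background on 1 of the 2 arrays. The uptake list had a median of -0.12 (-0.28 and 0.09 on the replicates; camera adjusted p = 0.34), and OsIRT1 stood at -0.12 ± 0.07. Fer2 was 1.58-fold higher (log2 0.66 ± 0.22, SD, n = 2; limma adjusted p = 1), while the second ferritin probe stood at 0.02 ± 0.17 and OsNAS3 had ratios of 0.62 and -0.48.

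Cytosolic ribosomal proteins rose in roots at 3 weeks under loess, with a median of 0.21 over 27 probes, 24 of them higher (camera adjusted p = 0.0073, adjusted p = 0.78 with an estimated correlation), but the median was -0.34 under median centring. Replicate 1 gave this value, with a median of 0.48 against -0.06 on replicate 2. Hemoglobin 1 (AK064054, 0.88 ± 0.52), an ethylene response factor (AK111775, 0.73 ± 0.05), the Ids3-like transcript (AK060318, 0.76 ± 0.30) and formate dehydrogenase (AK064610, 0.59 ± 0.05) were higher on both arrays. The peroxidases AK066855 (-1.46 ± 1.25), AK104633 (-1.40 ± 0.87) and AK099241 (-0.70 ± 0.22), alpha 1 tubulin (AK067721, 2-fold lower, SD 0.69) and methionine synthase (AK067726, -0.84 ± 0.06) were lower on both.

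In roots at 3 weeks 0 probes passed in limma (smallest adjusted p = 0.999) and 638 had an unadjusted p under 0.05 (332 higher, 306 lower; 958 with the slide as a block) against 937 expected by chance. Over 2-fold on both arrays were 7 probes, 5 of them (71.4%) with the same sign. All 5 were higher and had control levels of 16 or more, among the brightest on the array. The ribosomal list did not pass by fry (smallest adjusted p = 0.80 over all lists), under the strict filter, with 1 probe per description or without replicate 1 of this group.

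The change of the shoot response between 3 days and 3 weeks was tested as a difference, in which a constant dye bias cancels. Photosystem genes had a median of -0.55 at 3 days and 0.18 at 3 weeks, and the median difference was 0.73 (camera adjusted p = 6.3e-09, adjusted p = 0.66 with an estimated correlation), and Calvin cycle genes differed by 0.48 (adjusted p = 0.0046; 0.66 with an estimated correlation). Ribosomal protein genes went the other way, with a difference of -0.53 (adjusted p = 2.5e-07; 0.66 with an estimated correlation). The kinase AK059727 had ratios of -1.42 ± 0.01 at 3 days and 1.43 ± 0.26 at 3 weeks, a difference of 2.84 (limma adjusted p = 0.067), and Fer2 was lower at 3 weeks by a difference of -1.20 (adjusted p = 0.67). In limma 0 probes passed (smallest adjusted p = 0.0668; 1258 with an unadjusted p under 0.05), 3 lists passed by camera and 0 by fry for a shared direction (photosystem genes and the nitrate, ammonium and phosphate transporters by its mixed test, adjusted p = 0.037 each). Plants at 3 weeks were also older, in both channels.

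Between 3 days and 3 weeks in roots, the ratios of the glutathione S-transferases fell, with a median difference of -0.15 (camera adjusted p = 2.5e-05, adjusted p = 0.90 with an estimated correlation). OsGSTU3 (AK107435, difference -1.33) and OsGSTU12 (AK063773, -1.43) were examples, and the laccase AK103094 (-1.30) and the auxin-induced protein AK103553 (-1.67) differed in the same direction. Class III peroxidases differed by -0.09 (adjusted p = 0.0014; 0.90 with an estimated correlation), a difference of 0 under the strict filter on dim probes. The iron uptake list differed by 0.17 (adjusted p = 0.031; 0.90 with an estimated correlation; 0.088 with the slide as a block). In limma 0 probes passed (smallest adjusted p = 1; 152 with an unadjusted p under 0.05), and none of the 3 lists passed by fry.

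Roots and shoots differed at 3 days in 9 gene lists. Relative to shoots, roots had higher ratios for photosystem genes (difference 0.51, or 1.54 under median centring, camera adjusted p = 2.9e-07). Their median ratio was 0.01 in roots, where their median control levels of 6.81 and 7.62 lay no higher than those of all probes (7.63 and 7.62). Lower ratios were found in roots for metallothioneins (-1.62, or -0.34 without replicate 1 of the shoots, camera adjusted p = 0.012) and the iron uptake list (-0.24, camera adjusted p = 0.0036). In the shoots OsNAS1, AK063464 and OsNAS2 had little room to fall, at control levels of 6.40, 6.37 and 6.50. AK070304, at 9.45 there, had ratios of -0.28 in shoots and -1.48 in roots. Phenylalanine ammonia-lyase (AK067801) had a ratio of 0.96 in roots and -1.12 in shoots, and the hin1-like AK068115 of 1.14 and -1.17. Further differences were found for glutathione S-transferases (0.12; 0.029), P450 enzymes (0.04; 0.029), chlorophyll and heme synthesis (0.15; 0.043), Calvin cycle genes (0.14; 0.012), histones and cell cycle genes (-0.15; 0.012) and heavy-metal and ZIP transporters (-0.29; 0.038). With an estimated correlation the adjusted p was 0.65 for histones and 0.54 for each of the others, and the Calvin cycle and chlorophyll differences were both -0.03 under the strict filter on dim probes. In limma 0 probes passed (smallest adjusted p = 0.517; 692 with an unadjusted p under 0.05), and none of the 9 lists passed by fry. With the slide as a block 8 passed, without chlorophyll and heme synthesis (adjusted p = 0.077). With 1 probe per description in a list 2 passed, the photosystem genes (0.61) and the iron uptake list (-0.49), while the 3 metallothionein descriptions were too few for the test.

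At 3 weeks, roots had higher ratios than shoots for ribosomal protein genes (median difference 0.57; camera adjusted p = 4.1e-09) and lower ones for photosystem genes (-0.32; 4e-04), each with an adjusted p of 0.75 with an estimated correlation. Under median centring neither passed, with differences of 0.22 and -0.14, and with the scanner's ratio they were 0.77 and -0.75. OsPT1 (AK063990) had a ratio of 0.08 in roots and 1.33 in shoots, MtN3 (AK103266) of 0.04 and 1.32, and the potassium transporter HAK1 (AK100669) of -0.33 and 0.92. In limma 0 probes passed (smallest adjusted p = 1; 394 with an unadjusted p under 0.05), and neither list passed by fry.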

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

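The tests of a shared iron response and of the labelling of slide 2, and the tests of control levels of the uptake genes, were chosen after the results had been seen, as was the use of the list test on the differences between groups; the tests of brightness and of the iron sample were set before theirs.

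In 17 cases a list differed between times or tissues when the difference itself was tested. In 13 of them the list had passed in 1 or both of the groups compared, and in 4 in neither. Photosystem genes of shoots differed by 0.73 between 3 weeks and 3 days (adjusted p = 6.3e-09). Calvin cycle genes of shoots differed by 0.48 (0.0046) and cytosolic ribosomal proteins by -0.53 (2.5e-07). In roots, 3 weeks minus 3 days, glutathione S-transferases differed by -0.15 (2.5e-05) and the iron uptake list by 0.17 (0.031), and class III peroxidases, which passed in neither group, by -0.09 (0.0014). Between roots and shoots at 3 days, metallothioneins differed by -1.62 (0.012), a value of -0.34 without replicate 1 of the shoots. Photosystem genes differed by 0.51 (2.9e-07), Calvin cycle genes by 0.14 (0.012), chlorophyll and heme synthesis by 0.15 (0.043), glutathione S-transferases by 0.12 (0.029), P450 enzymes by 0.04 (0.029) and the iron uptake list by -0.24 (0.0036). Of the uptake list, OsNAS1, OsNAS2 and AK063464 lay near background in these shoots, with little room to fall. Heavy-metal and ZIP transporters (-0.29, 0.038) and histones and cell cycle genes (-0.15, 0.012) differed there but passed in neither tissue. At 3 weeks, ribosomal proteins of roots minus shoots differed by 0.57 (4.1e-09), and photosystem genes, which passed in neither tissue at that time, by -0.32 (4e-04). None of the 17 passed with a correlation estimated from the data, where the adjusted p ranged from 0.54 to 0.90.

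The log ratios of the 2 arrays of a group barely correlated across probes. Over the 6664 probes of the strict filter on dim probes, the mean correlation of replicates was 0.02 (range -0.13 to 0.18). For a weak iron channel on slide 1 as the cause, this value cannot decide, since every pair of replicates includes an array of slide 1. Over the same probes, different groups correlated at a mean of 0.1 on slide 1 (range -0.13 to 0.43). On slide 2 that mean was 0.47 (range 0.3 to 0.56). A weak iron channel on slide 1 thus stays open. For an iron response shared by all groups, the mean of 0 between different groups across slides cannot decide. Replicates of a group share their iron response, and they too correlated across slides at a mean of only 0.03. Different groups on slide 2 correlated by 0.40 more than groups on different slides, but labelling of that slide and a property of the replicate 2 plants cannot be told apart, as each replicate stood on 1 slide. Biological differences between the pools of plants stay open and were not tested.

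The uptake genes OsNAS1, OsNAS2, AK063464 and AK070304 were lower in roots at 3 weeks on replicate 1 (mean -2.71, range -3.56 to -1.44) and not on replicate 2 (mean 0.13, range 0.04 to 0.30). The dim iron channel of replicate 1 as the cause was argued against by their median percentile of 0.17 among probes of like control brightness on that array. Control roots of replicate 2 already near background were argued against too, since 4 of the 4 were well above background there. Control levels on replicates 1 and 2 were 12.20 and 10.24 for OsNAS2, 11.72 and 9.88 for OsNAS1, 10.55 and 8.09 for AK063464 and 9.39 and 9.36 for AK070304. Lower control levels as the whole cause were argued against for OsNAS2, OsNAS1 and AK070304, whose iron levels lay higher on replicate 2 by at least 1.49 (8.65 and 10.53, 8.41 and 9.92, 7.95 and 9.44). For AK063464, with a gap of 0.14, they stay open, as its control level on replicate 2 was already at its iron level on replicate 1 (8.04). A weak or missing iron response in the iron sample of replicate 2 remains a candidate explanation: the 52 probes over 2-fold higher on both root arrays at 3 days had a median of 0.16 there (38 higher), against 0.73 on replicate 1 (44 higher). Log ratios on slide 1 were also more spread, and a difference between the pools of plants was not tested.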

How the results depend on the processing

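Scaling between arrays, array weights, 1 probe per description in a list, the trended and robust spread, slide 2 alone and the list test on differences were chosen after the data were seen. Over 22 settings, the counts of called probes, all 0 as reported, stayed 0 in 80 cases and rose in 8 for the 4 responses, and in 84 and 4 for the 4 differences. A count of 0 that stays 0 is a floor and is no measure of stability. List counts, also over 22 settings, stayed within 1.5 times the value reported in 120 cases and moved in 56. Shifts of called lists, over 23 settings, kept direction, and where tested the threshold, in 470 cases, lost the threshold in 169 and changed direction in 8. Part of this agreement was fixed in advance and is no measure of stability. Quantile normalization of the average intensities leaves the ratios unchanged, and the deposited log ratios repeat the scanner's. Leaving out an array of another group cannot move a group's median, though it can move the p. With an estimated correlation the number of lists called was 0 in shoots at 3 days, 0 in shoots at 3 weeks, 0 in roots at 3 days and 0 in roots at 3 weeks, and with fry for a shared direction it was 0, 0, 0 and 0. Unless said otherwise the cause of a change was not tested.

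Against 0 called probes in limma as reported, roots at 3 days had 1 without background correction and 6 with array weights, and shoots at 3 days had 24 with scaling between arrays, all lower. In shoots at 3 weeks 1 was called with the replicate block (the slide in the fit, which takes up what the arrays of a slide share), and for the shoot difference between times 1 with the strict filter, which tests fewer probes, and 1 with the trended and robust spread. Leaving out 1 array gave 0 to 1 calls in shoots at 3 weeks (1 without replicate 1), 0 to 14 in roots at 3 days, 0 to 6 for the root difference between times and 0 to 10 for the tissue difference at 3 days, the highest each without replicate 2 of roots at 3 days; roots at 3 days had 1 call, RAB24 (AK073273), without either array of roots at 3 weeks. A lone array is here assumed to vary like the other groups.

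The scanner software's log ratio and the deposited table each called 3 lists in shoots at 3 days, 2 in shoots at 3 weeks and 3 in roots at 3 weeks. Median centring called 3 in shoots at 3 weeks, as did the arrays of that group alone, and the strict filter 2 in roots at 3 days and 0 in roots at 3 weeks. With 1 probe per description in a list 0 were called in roots at 3 weeks (median of the ribosomal list 0.16) and 2 of 9 in the tissue difference at 3 days. Leaving out 1 array gave 2 (without replicate 2) to 8 lists in shoots at 3 days, 1 to 9 in shoots at 3 weeks (9 without replicate 1, 1 without replicate 2 of roots at 3 days, 2 or 3 without any other array), 4 to 9 in roots at 3 days (9 without replicate 1) and 0 (without replicate 1) to 5 (without replicate 2) in roots at 3 weeks.

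The list tests turned direction, or on slide 2 alone the medians did, as follows: ribosomal proteins of roots at 3 weeks to -0.34 under median centring and to -0.06 on slide 2 alone (-0.06 to 0.48 leaving out 1 array, the lowest without replicate 1); metallothioneins of shoots at 3 days to -0.18 on slide 2 alone; and under the strict filter the Calvin cycle of shoots at 3 days to 0.15, the tissue difference of the Calvin cycle at 3 days to -0.03 and the root difference of peroxidases to 0. The root difference of the uptake list ranged from 0.04 to 0.22 leaving out 1 array, and at 0.04, without replicate 2 of roots at 3 weeks, the direction of its test turned. Other medians took the other sign while the test kept its direction and lost the threshold: the tissue difference of chlorophyll and heme synthesis at 3 days (-0.03 under the strict filter), P450 enzymes of roots at 3 days (-0.03 without replicate 2 of that group), the tissue difference of heavy-metal and ZIP transporters (0.01 without replicate 1 of roots at 3 days), metallothioneins of shoots at 3 days (-0.18 without replicate 1), and the Calvin cycle of shoots at 3 days and its tissue difference (0.08 and -0.05 without replicate 2 of these shoots).

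Over all settings the medians ranged from 0.05 to 0.37 for the ribosomal list and from -0.43 to -0.06 for ABC transporters in shoots at 3 days. They ranged from -0.69 to -0.10 for the ribosomal list of shoots at 3 weeks, and from 0.11 to 0.39 for glutathione S-transferases and 0.07 to 0.34 for pathogenesis-related proteins in roots at 3 days. The tissue differences at 3 weeks ranged from 0.22 to 0.94 (ribosomal) and from -0.75 to -0.14 (photosystem).

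Of 94 named gene results, 11 changed sign in some setting. Fer2 did not, but in roots at 3 weeks its log2 ratio ran from 0.11 to 0.82 over all settings. Under median centring AK106026 stood at -0.13 and -0.11 in shoots at 3 days and 3 weeks, AK060318 at -0.09 in roots at 3 days and AK070753 at -0.12 in roots at 3 weeks. Left out in turn, the 2 arrays of a group gave -0.35 to 1.24 for AK106026, -0.12 to 4.69 for AK103445 (shoots at 3 days) and -0.74 to 0.16 for OsIRT1 (AK103730, roots at 3 days). In roots at 3 weeks the ranges were -3.56 to 0.30 for OsNAS2, -3.31 to 0.04 for OsNAS1, -2.51 to 0.09 for AK063464, -1.44 to 0.08 for AK070304, -0.10 to 0.13 for AK106026 and -0.05 to 1.34 for AK070753. Except for AK106026 in shoots at 3 days, the value of the changed sign is that without replicate 1 and that on slide 2 alone. The share of higher probes among those with an unadjusted p under 0.05 also moved: from 28.6%, 79.7%, 61.7% and 52% (groups in the report's order) to 5.7%, 17.5%, 9.6% and 34.8% under median centring and 36.3%, 52.2%, 43.3% and 41.2% with the scanner's ratio. Median centring set the median of all probes in roots at 3 days to -0.171 on the log2 scale, against which its ratios are to be read. Signal over background limits the ratios of slide 1 most, where as few as 36.1% of iron-channel spots were well above background.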

Other observations

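The test of phosphate starvation markers was chosen after the ratios of OsPT1, a purple acid phosphatase, a ribonuclease and an ids4-like transcript in shoots at 3 weeks had been seen; the test of a dye bias was set before its result.

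Of 25 probes described as phosphate starvation markers, 22 were higher on the mean of both arrays in shoots at 3 weeks. Some differed in size or sign between the replicates, and none passed in limma. Monogalactosyldiacylglycerol synthase (AK064148), which makes a lipid without phosphorus, had log2 ratios of 4.13 and 0.91, the purple acid phosphatase AK070684 of 0.90 and 0.94 and the phosphate transporter Pht1-2 (AK101380) of 0.65 and 0.63. A second ids4-like transcript (AK063544) stood at 1.56 and 0.57, and the purple acid phosphatase PAP22 (AK073222) at 1.04 and 0.65. The S-like ribonuclease AK059757 was lower, at -0.68 and -0.62. A second Pht1-2 probe (AK101170) stood at -0.46 and 0.63, and 2 probes of the digalactosyldiacylglycerol synthase DGD2 at -0.15 and -0.22 (AK102684) and at 0.47 and -0.06 (AK067931).

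A phosphate starvation response of these shoots is a candidate explanation. Markers already named, or among the leading or over 2-fold probes of this group, were left out. The 21 other probes had a median of 0.29, and 19 of them were higher (replicate medians 0.47 and 0.30; camera p = 0.001; p = 0.023 with an estimated correlation). They are not an independent set, since AK063544 and AK066273 share their descriptions with the left-out AK107245 and AK071643. The list of nitrate, ammonium and phosphate transporters had also been tested in this group. A first version that left out only the markers seen to be higher kept 22 probes, with a median of 0.29, p = 0.01 and p = 0.051 with an estimated correlation; all 25 had a median of 0.33 (p = 0.00011 and p = 0.027). The median of the 21 was 0.26 under median centring and 0.50 with the scanner's ratio. A constant dye bias of these probes was argued against by the difference between shoots at 3 weeks and at 3 days, a median of 0.38 (18 of 21 higher; p = 0.0049; p = 0.037 with an estimated correlation). The same probes had medians of -0.01 in shoots at 3 days (p = 0.67), 0.05 in roots at 3 days (p = 0.11) and 0.25 in roots at 3 weeks (17 of 21 higher; p = 0.00021; p = 0.015 with an estimated correlation). These p-values are not adjusted, and the words for the list were chosen after the first genes had been seen.

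Lists called by camera were compared with 10000 random lists of like size and of like brightness averaged over all arrays, roots and shoots together. The photosystem list of shoots at 3 days (median -0.55) lay at percentile 0. Its random medians ran from -0.08 to 0.11 once the lowest and highest 2.5% were left out. The metallothionein list there (1.08) lay at percentile 100, with random medians from -0.29 to 0.40. In roots at 3 days the uptake list (-0.24) lay at percentile 0, with random medians from -0.10 to 0.07, the glutathione S-transferases at percentile 100 and the P450 enzymes at percentile 88.36. Random lists do not share a correlation between members, as these lists can. As the lists had been called on the same data, an extreme percentile is no independent test of that call. Median control levels of the photosystem probes were 13.92 and 12.86 in shoots at 3 days and 6.81 and 7.62 in roots at 3 days. Their averaged brightness thus lay below that in shoots, so the comparison cannot tell whether their fall goes with brightness there.

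The control levels of OsNAS2 (AK112011) on the root arrays differed between replicates: 9.17 and 13.22 at 3 days and 12.20 and 10.24 at 3 weeks on the log2 scale, against 8.04, 7.85, 8.65 and 10.53 in the iron channel. Above 0.5 on all 8 arrays was 1 probe, AK106985, described only by its similarity to an Arabidopsis sequence (mean 1.60, range 0.72 to 2.88; with the scanner's ratio -0.19 on replicate 1 of roots at 3 weeks and 1.03 to 1.86 on the others), and 0 probes were below -0.5 on all 8. This probe was among the brightest, and very bright probes were mostly higher in every group: of the 12, 15, 20 and 14 probes with a control level of 16 or more (groups in the report's order), 10, 14, 15 and 11 were higher, with medians of 1.08, 1.03, 0.83 and 1.26, and of 0.61, 0.66, 0.72 and 0.72 with the scanner's ratio. They made up 1 of the 41, 6 of the 25, 6 of the 60 and 5 of the 5 probes over 2-fold on both arrays with the same sign. In shoots at 3 weeks these included probes described as chloroplast ribosomal RNA (AK060185), small subunit ribosomal RNA (AK062665) and the large subunit of Rubisco (AK058623). Of all probes with a control level of 16 or more, 1, 3, 0 and 2 were marked as saturated on an array. The cause was not tested.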
